A study of Mus musculus with 8 samples.

How the data were processed

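RNA was measured in mouse embryonic stem cells of a hybrid line, CAST/Ei x 129/Sv/Jae, that were either wild type (WT) or carried the HNRNPK 6A mutation. HNRNPK is an RNA-binding protein of the hnRNP family that links Xist, the RNA that coats the inactive X chromosome, to Polycomb repression. What the 6A mutation substitutes is not given in the sources used here. Per the labels, undifferentiated cells grew on irradiated mouse embryonic fibroblast feeders, which were removed before harvest at day 0. Other cells were taken off leukemia inhibitory factor, grew in suspension for 4 days as embryoid bodies, were plated at day 5 and were harvested at day 14. The series' design sentence names day 7 for the differentiated cells, whereas each sample's title, cell type and protocol name day 14, which is used here. Each of the 4 groups had 2 libraries, which the protocol calls biological replicates.

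Total RNA was depleted of ribosomal RNA, made into directional libraries and sequenced as 150-base paired-end reads. The submitters' notes name cutadapt 1.4.2, STAR 2.7.10a and the genome build mm10. The tool that counted reads, its strand setting, the gene annotation and the method that gave reads to an allele are not given in the sources used here. The deposited tables hold raw counts for 24421 genes in each of the 8 libraries, with the count of all reads and the counts of reads given to the CAST and to the 129 genome. They were whole numbers, and the allele counts of a gene never exceeded its count of all reads. Symbols were matched to GENCODE mouse release 21, where 23264 matched directly and 666 through an older symbol, 97.99% in total, while 491 did not match.

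Changed genes were called from the counts of all reads with edgeR 4.0.16 under R 4.3.3. Genes were kept by filterByExpr on the group, which left 15458, and libraries were scaled by TMM. A quasi-likelihood model with robust dispersion was fitted to all 8 libraries with 1 coefficient per group, which left 4 residual degrees of freedom, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The common biological coefficient of variation was 0.111. The 5 contrasts were 6A against WT at day 0, 6A against WT at day 14, day 14 against day 0 in WT and in 6A, and the genotype by day interaction, which is the 6A difference at day 14 minus that at day 0. Values in the text are normalised read counts (CPM, counts scaled to the TMM-adjusted library size) as mean ± SD over the 2 libraries of a group, and log2 fold changes ± their standard error. With 2 libraries against 2, an exact permutation test of a single gene cannot go below p = 0.333 (two-sided), so p-values rest on the spread that the model shares across genes. They measure only the spread between these samples, since the labels do not say whether the 2 libraries of a group came from separate cultures, differentiations or clones.

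The tests, the main settings, most alternatives, 33 gene lists and the rule for named genes were fixed before the data were examined. The lists cover X inactivation, RNA-binding and Polycomb factors, cell types of early embryos and differentiating cultures, stress and growth programmes, and RNA classes. Of these, 32 had members in the tables, the exception being mitochondrially encoded genes, and 30 had the 5 tested members needed for a test. Each was tested in the 5 contrasts, 150 tests in all, with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted together. For members, calls are given over all genes and adjusted over the list alone. X-linked protein-coding genes (553 tested) were compared with the other genes by camera, and every chromosome was tested in the same way. The change of X-linked genes was correlated with distance from Xist by Spearman's rho, with a permutation p from circular shifts along the chromosome. The named genes are Hnrnpk, Xist and Tsix, the 10 largest rises and 10 largest falls among called genes with a mean of at least 1 CPM and no overlap between the groups (5 and 5 in the interaction, without the overlap condition), up to 4 members of each list by smallest adjusted p, and called genes of the X inactivation center. Predicted genes and pseudogenes were passed over, and a few genes that the rule named are not reported here.

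The comparison of allele reads was chosen after seeing the data. It used genes with a mean of at least 10 allele-assigned reads per library, 432 on the X chromosome and 3949 autosomal genes with a 129 share of 0.2 to 0.8. Log2 ratios of 129 to CAST reads were fitted in edgeR with the same groups, and X-linked genes were set against the autosomal genes with camera. The share of 129 reads of single genes at day 14 is given for genes with at least 100 reads in both groups.

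Totals ran from 8146684 to 15540163 counts per library, so a floor of 3 counts corresponded to between 0.193 and 0.368 CPM in a single library, scaled to total counts without the TMM factor. The Y-linked sums are scaled in the same way. Where a group had 0 counts of a gene, the fold is a lower bound against 3 counts pooled over the group, and where it had 1 to 3 counts the ratio is given with an exact 95% interval. Shares of single libraries have Wilson 95% intervals. Intervals and floors cover counting error only. The alternatives were DESeq2 1.42.0, limma-voom, RLE, upper-quartile and total-count scaling, leaving out the 20 most counted genes, no filter or a stricter filter on low counts, protein-coding genes only, a block for the replicate number, only the 2 groups compared, an absolute log2 fold change over 1, an estimated correlation in camera, and leaving out each library in turn. Leaving out genes marked by feeder RNA and the alternatives for the allele ratio were added after seeing the data. Sets were also tested with fry, which asks whether a set moved in 1 direction and does not compare it with other genes. When a group was left with 1 library, that library was assumed to vary like the other groups.

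The procedure was tested on simulated data of the same size and depth. At day 0 it recovered 73% of 100 genes changed 2-fold and 91% of 100 changed 4-fold, with 17 of the unchanged genes called. The figures at day 14 were 82% and 97%, with 20 unchanged genes called. Unchanged genes made up 8.9% of the calls at day 0 and 9.9% at day 14, more than an adjusted p under 0.05 aims at. Genes were simulated independently of each other, so spread that genes share within a library was not covered. With no gene changed it called 8 genes at day 0 and 0 at day 14. Figures were drawn with matplotlib 3.10.9, and tables were handled with pandas 2.3.3 and SciPy 1.17.1 under Python 3.11.15.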

Results

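RNA was sequenced from hybrid CAST/Ei x 129/Sv/Jae mouse embryonic stem cells, either WT or carrying the HNRNPK 6A mutation, in the undifferentiated state (day 0) and as embryoid body cultures at day 14. The series is about the spreading of Xist along the X chromosome. The comparisons cover the effect of the mutation before and after differentiation, the changes of each genotype on differentiation, and the X chromosome against the autosomes. Each of the 4 groups had 2 libraries. The total counts were 8618779 and 15269189 for WT at day 0 and 12425526 and 15540163 for 6A at day 0. At day 14 they were 8146684 and 11655053 for WT and 9922988 and 9882947 for 6A. Between 29.1% and 31.6% of the counts were assigned to 1 of the 2 parental alleles.

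Hnrnpk (mm10, chromosome 13, 58391142 to 58403343, minus strand) was lower in the mutant at both times. It fell from 794 ± 121 CPM in WT to 533 ± 7.54 in 6A at day 0 (SD, n = 2 each; log2 fold change -0.58 ± 0.12, edgeR adjusted p = 0.040). At day 14 it fell from 485 ± 15.1 to 366 ± 26.3 (log2 fold change -0.40 ± 0.12, adjusted p = 0.043). Xist (X chromosome, 103460366 to 103483254, minus strand) did not differ between genotypes by the test. It stood at 65.4 ± 10.8 CPM in WT and 59.7 ± 7.11 in 6A at day 0 (adjusted p = 0.69). At day 14 it stood at 1142 ± 22.4 and 966 ± 75.2 (log2 fold change -0.24 ± 0.13, adjusted p = 0.27). Tsix, the antisense RNA that overlaps Xist (103431517 to 103484957, plus strand), was at 68.8 ± 4.70 and 69.5 ± 0.523 CPM at day 0 and at 4.43 ± 0.785 and 5.50 ± 0.681 at day 14 (adjusted p = 0.98 and 0.33). Whether the counts separate the strands is not given in the sources used here, so reads of the overlap cannot be placed with certainty. The call of Hnrnpk at day 0 was lost in every fit without a library except the fit without WT day 0 replicate 2 (adjusted p from 0.0099 to 0.26). It was also lost with only the 2 groups fitted (adjusted p = 0.18). The call at day 14 was lost in every fit without a library except those without a WT day 0 library (adjusted p from 0.0097 to 0.29), and with DESeq2 (0.074), RLE (0.069) and no filter on low counts (0.063). Its log2 fold change was negative in all of them.

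In undifferentiated cells, 8 of the 10 largest rises in 6A were X-linked genes. Scml2, a Polycomb-related protein of the testis, rose from 15.4 ± 2.40 CPM in WT to 81.1 ± 2.57 in 6A (SD, n = 2; log2 fold change 2.38 ± 0.14, adjusted p = 3.6e-06). Usp26, a deubiquitinase of the testis, rose from 35.9 ± 10.1 to 169 ± 5.64 CPM (2.25 ± 0.16, adjusted p = 2.1e-05). Efhc2, an EF-hand protein, rose from 8.51 ± 3.15 to 46.4 ± 1.73 (2.49 ± 0.21, adjusted p = 9.6e-05). Among less abundant X-linked genes, Xlr5a rose from 1.30 ± 0.435 to 8.85 ± 0.791 CPM (adjusted p = 0.00041), Xlr4a from 1.73 ± 0.348 to 8.43 ± 0.0698 (adjusted p = 0.0068). Mageb16 rose from 0.90 ± 0.225 to 4.35 ± 0.463, Pramel3 from 0.476 ± 0.374 to 3.52 ± 0.0229 and Pet2 from 0.538 ± 0.238 to 3.70 ± 0.521. The remaining 2 of the 10 largest rises were autosomal, Nlrp4c (1.45 ± 0.0485 to 6.26 ± 1.72 CPM) and Lgi3 (31 counts in 6A against 2 in WT, a ratio of 12.9 with a 95% interval of 3.29 to 112). Xlr, Pramel and Nlrp4 genes belong to families of close copies, and how reads were shared among the copies is not given in the sources used here.

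The 10 largest falls at day 0 are given next. Lef1, a transcription factor of Wnt signalling, fell from 9.12 ± 2.08 CPM in WT to 2.08 ± 0.167 in 6A (log2 fold change -2.14 ± 0.26, edgeR adjusted p = 0.0012). Ap1m2, an epithelial clathrin adaptor subunit, fell from 12.9 ± 2.03 to 2.67 ± 0.572 (-2.27 ± 0.24, adjusted p = 0.00043). Fgf5, a growth factor of primed pluripotency, had 36 counts in WT and 2 in 6A, a ratio of 21.6 (95% interval 5.55 to 185, adjusted p = 0.0075). Vrtn, a transcription factor that acts on vertebral number, fell from 9.34 ± 2.32 to 3.14 ± 0.281 CPM. Sfrp4, a secreted Wnt modulator, fell from 6.33 ± 0.468 to 2.04 ± 0.620. The others were Egr4 (1.75 ± 0.0267 to 0.329 ± 0.102 CPM), Arhgef16 (3.89 ± 0.0911 to 0.986 ± 0.306), Atcay (1.91 ± 0.0979 to 0.481 ± 0.0753), Wdr86 (4.93 ± 0.881 to 1.36 ± 0.131) and Flywch2 (2.98 ± 0.321 to 0.938 ± 0.00421). In total, 244 of 15458 genes changed at day 0, 164 higher and 80 lower in 6A. That count depended on single libraries. It was 567 and 160 without WT day 0 replicate 1 or 2, and 57 and 32 without 6A day 0 replicate 1 or 2. It was 78 and 82 without WT day 14 replicate 1 or 2, and 148 and 146 without 6A day 14 replicate 1 or 2. It was 23 when only the 2 groups were fitted, 459 without a filter on low counts, 466 with the replicate number as a block, and 93 with an absolute log2 fold change over 1.

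**Figure D1:**
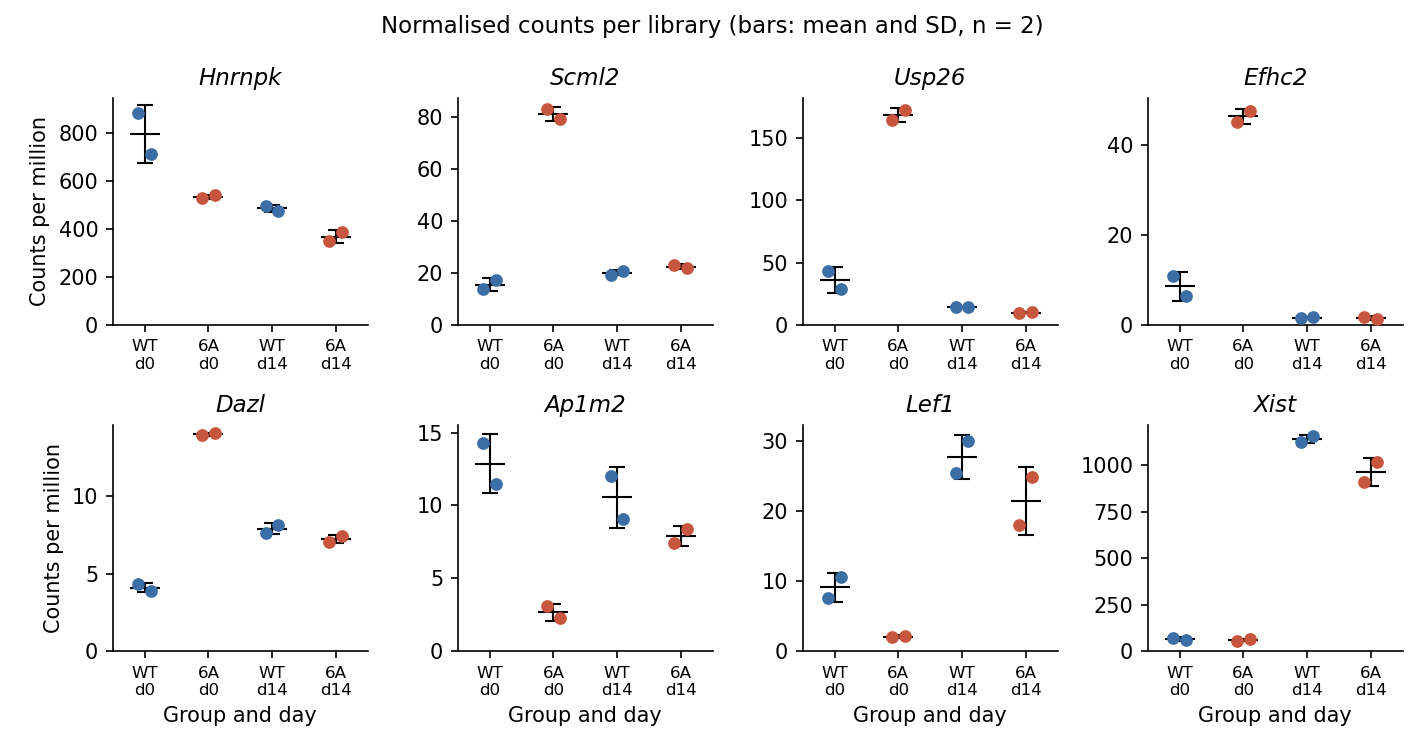
Normalised read counts (CPM) of 8 genes in each of the 8 libraries, with points for libraries and black bars for the mean and SD of each group (n = 2), WT in blue and 6A in red. Scml2, Usp26, Efhc2 and Dazl were higher in both 6A libraries at day 0 and Ap1m2 and Lef1 lower, while Xist had group means of 59.7 and 65.4 CPM at day 0 and of 966 and 1142 CPM at day 14.

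Feeder RNA was measurable at day 0. The sum over 6 Y-linked genes, scaled to total counts without the TMM factor, was 0 in both WT libraries and 0.101 and 0 CPM in the 6A libraries at day 14. At day 0 it was 26.6 and 26.1 CPM in WT and 40.9 and 45.2 CPM in 6A, a ratio of 1.63. Genes read from both alleles at day 14 but nearly only from the 129 allele at day 0 (132 genes) had a median log2 fold change of 0.34 in 6A against WT at day 0, and 3 of them were called higher. Without 156 genes marked by feeder RNA, 210 genes changed at day 0, 128 higher and 82 lower. With these genes kept and RLE scaling the count was 213, 131 higher and 82 lower. The drop from 244 can therefore not be assigned to feeder RNA. The fibroblast and mesenchyme list moved in the direction of the Y-linked sums. Its 24 tested members had a median log2 fold change of 0.36 (camera adjusted p = 5.6e-09; adjusted p = 0.11 with an estimated correlation). Of these, 2 rose, or 12 when adjusted over the list alone. Lox, which crosslinks collagen, rose from 85.7 ± 1.85 to 132 ± 1.25 CPM (edgeR adjusted p = 0.011) and Postn, a matrix protein, from 40 ± 3.78 to 57.7 ± 2.36 (adjusted p = 0.042).

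Germline genes were higher in 6A at day 0 (14 tested members, median log2 fold change 0.67, camera adjusted p = 2.3e-09; adjusted p = 0.088 with an estimated correlation). Dazl, an RNA-binding protein of germ cells, rose from 4.10 ± 0.308 to 14.0 ± 0.105 CPM (log2 fold change 1.78 ± 0.19, edgeR adjusted p = 0.00043). Asz1, of the piRNA pathway, rose from 0.802 ± 0.436 to 2.90 ± 0.611 (adjusted p = 0.0499). Adjusted over the list alone, 8 members rose. Interferon response genes (18 members) had a median of 0.20, with 3 higher when adjusted over the list alone (camera adjusted p = 0.0017; adjusted p = 0.27 with an estimated correlation). Both lists moved in the direction of the Y-linked counts, which were 1.63 times as high in 6A as in WT. Whether feeders supplied RNA of these lists was not tested, and the rise of Dazl was larger than that ratio. The X inactivation center list had a median of 0.35 (adjusted p = 0.0030; adjusted p = 0.41 with an estimated correlation), with 1 of 10 members called and 3 when adjusted over the list alone. Tsx, a noncoding gene beside Xist, rose from 2.54 ± 0.102 to 6.60 ± 0.0177 CPM (adjusted p = 0.024).

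Lower lists at day 0 were replication-dependent histones (60 members, median log2 fold change -0.45, camera adjusted p = 2.8e-09; adjusted p = 0.44 with an estimated correlation) and ribosomal proteins (81 members, -0.17, adjusted p = 3.9e-05; adjusted p = 0.48 with an estimated correlation). So were formative and primed pluripotency (14 members, -0.20, adjusted p = 0.00020; adjusted p = 0.20 with an estimated correlation) and glycolysis and hypoxia (20 members, -0.20, adjusted p = 0.0024; adjusted p = 0.28 with an estimated correlation). Of the primed genes 2 fell, Lef1 and Fgf5, or 4 adjusted over the list alone, where 1 rose. Of the hypoxia genes 1 fell, or 2 adjusted over the list alone. Egln3, an oxygen-sensing prolyl hydroxylase, went from 10.7 ± 0.239 to 5.02 ± 0.0808 CPM (edgeR adjusted p = 0.0060). Abundant small structural RNAs (8 members, median -0.54, adjusted p = 0.023; adjusted p = 0.38 with an estimated correlation) included Terc, the telomerase RNA, which fell from 150 ± 19.3 to 87.2 ± 0.779 CPM. Endothelial genes (15 members, -0.24, 2 lower when adjusted over the list alone) passed narrowly (adjusted p = 0.047; adjusted p = 0.48 with an estimated correlation). Some of these calls rested on single libraries. Without WT day 0 replicate 1 the small RNAs (median -0.033, adjusted p = 0.81), ribosomal proteins (-0.053, 0.26) and glycolysis and hypoxia (-0.15, 0.070) were not called. Without 6A day 0 replicate 2 the small RNAs (-0.28, 0.076), glycolysis and hypoxia (-0.12, 0.080) and endothelial genes (-0.11, 0.16) were not called, and the histone median was -0.29. Without WT day 0 replicate 2 the X inactivation center (adjusted p = 0.066) and endothelial genes (-0.12, 0.58) were not called, and the primed pluripotency median was -0.066 (adjusted p = 0.014). Endothelial genes were also not called with RLE (adjusted p = 0.055), with the replicate block (0.058) or without 6A day 14 replicate 1 (0.052).

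The other lists were not called at day 0. Single members were called in 4 of them. Krt18, a keratin of trophoblast and other epithelia, fell from 9.99 ± 1.05 to 5.59 ± 1.29 CPM (edgeR adjusted p = 0.035). Hoxd13 rose from 24.3 ± 0.822 to 39.3 ± 4.08 (adjusted p = 0.040) and the macrophage lysozyme Lyz2 from 1.24 ± 0.161 to 3.25 ± 0.601 (adjusted p = 0.030). The Polycomb subunit Bmi1 rose from 22.4 ± 4.62 to 36.1 ± 0.502 (adjusted p = 0.0499). The medians were -0.25 for trophoblast (camera adjusted p = 0.051), -0.14 for proliferation (0.076) and -0.13 for the integrated stress and unfolded protein response (0.099). They were -0.23 for neural (0.13), -0.39 for cardiac muscle (0.16), 0.09 for p53 targets (0.18), 0.24 for Hox genes (0.19) and -0.06 for naive and general pluripotency (0.21). X-linked genes that escape inactivation had 0.11 (0.25), and primitive streak and mesendoderm had -0.12 (0.25). The medians were 0.13 for imprinted genes (0.38), 0.08 for extracellular matrix and basement membrane (0.39), -0.04 for the hnRNP family (0.51) and 0.23 for Kcnq1ot1 and Airn target genes (0.51). Next came -0.08 for immediate early genes (0.51), 0.02 for Polycomb subunits (0.58), 0.03 for endoderm and yolk sac endoderm (0.62), -0.02 for Xist silencing and localization factors (0.74), 0.10 for blood (0.77) and 0.10 for nuclear long noncoding RNAs (0.80). With genes at the counting floor set to their bounds, the medians were -0.18 for neural, -0.44 for cardiac muscle, -0.49 for primitive streak, 0.17 for extracellular matrix, 0.16 for Kcnq1ot1 and Airn targets and 0.29 for endoderm. Of the 32 named genes that passed at day 0, Scml2, Usp26, Efhc2, Xlr5a, Ap1m2, Lef1 and Dazl did so in every alternative. The other 25 lost the call without at least 1 library. It was lost by 23 of them without 6A day 0 replicate 2 (adjusted p 0.081 to 0.35) and 18 without WT day 0 replicate 2 (0.052 to 0.25). Without the other libraries the losses were 14 without 6A day 0 replicate 1 (0.053 to 0.20), 15 and 14 without WT day 14 replicate 1 or 2 (up to 0.10), 7 without either 6A day 14 library (up to 0.070) and 2 without WT day 0 replicate 1 (up to 0.060).

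X-linked genes as a whole were higher in 6A than in WT at day 0. The median log2 fold change of 553 X-linked protein-coding genes exceeded that of the autosomal genes by 0.157 (camera adjusted p = 4.5e-09; adjusted p = 0.27 with an estimated correlation). Of these genes, 400 had a higher and 149 a lower fitted value in 6A, and 37 rose and 2 fell past the threshold. The 37 were 45 and 19 without WT day 0 replicate 1 or 2, 18 and 11 without 6A day 0 replicate 1 or 2, 17 and 18 without WT day 14 replicate 1 or 2, 26 without either 6A day 14 library and 9 with only the 2 groups fitted. X-linked genes took 4.73% and 4.95% of the counts in the 6A libraries and 4.61% and 4.42% in the WT libraries. The X chromosome was the only chromosome called in this comparison. The excess ran from 0.115 without WT day 0 replicate 2 to 0.20 without WT day 0 replicate 1.

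At day 14, 6A cultures had far less neural and cardiac RNA and more blood RNA than WT cultures. The neural list had a median log2 fold change of -3.38, with 19 of 23 members lower and 21 when adjusted over the list alone (camera adjusted p = 9.7e-60; adjusted p = 0.0048 with an estimated correlation). Map2, a microtubule protein of neurons, fell from 50.7 ± 5.08 to 7.53 ± 0.412 CPM (SD, n = 2; log2 fold change -2.75 ± 0.16, edgeR adjusted p = 1.9e-07). Zic1, a neural transcription factor, fell from 45.5 ± 2.34 to 3.57 ± 0.409 (-3.67 ± 0.22), and Tubb3, neuronal tubulin, from 55.8 ± 8.13 to 11.1 ± 0.481 (-2.33 ± 0.15). The cardiac muscle list had a median of -2.10, with 19 of 23 members lower over all genes and over the list alone (adjusted p = 1.7e-53; adjusted p = 0.0048 with an estimated correlation). The ventricular myosin Myh7 fell from 169 ± 1.74 to 8.01 ± 1.5 CPM (-4.40 ± 0.16, adjusted p = 5.9e-09). The atrial myosin Myh6 fell from 253 ± 0.876 to 24.6 ± 0.689, cardiac actin Actc1 from 81.1 ± 10.8 to 8.88 ± 1.5 and titin, Ttn, from 819 ± 117 to 153 ± 3.11.

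Blood genes rose, with a median log2 fold change of 1.21, 13 of 18 members higher and 15 when adjusted over the list alone (camera adjusted p = 6.1e-27; adjusted p = 0.027 with an estimated correlation). The embryonic globins rose most. Hba-x rose from 0.390 ± 0.104 to 28.3 ± 0.948 CPM (log2 fold change 6.19 ± 0.37, edgeR adjusted p = 2.9e-07), and Hbb-bh1 from 0.451 ± 0.146 to 29.2 ± 1.99 (5.93 ± 0.28, adjusted p = 5.1e-08). Hbb-y rose from 0.329 ± 0.354 to 17.5 ± 1.16 (5.89 ± 0.44, adjusted p = 2.1e-06). Lyz2, of macrophages, rose from 9.65 ± 0.451 to 28.9 ± 0.334 CPM. The other largest rises held further red cell genes, Pklr (23 counts in 6A against 1 in WT, ratio 23.6, interval 3.84 to 973) and the anion exchanger Slc4a1 (0.253 ± 0.134 to 2.85 ± 0.887 CPM). They also held the placental gene Tpbpa (0.451 ± 0.146 to 5.50 ± 0.545), the water channel Aqp8 (0.369 ± 0.298 to 3.91 ± 1.16), the osteoclast protease Ctsk (2.67 ± 1.48 to 29.9 ± 2.94) and Xdh (0.213 ± 0.190 to 1.79 ± 0.477).

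The 10 largest falls included genes with 1 to 3 counts in 6A. There were 349 counts in WT against 1 in 6A of Six3os1 (ratio 340, 95% interval 60.6 to 13461). Hes5 had 296 against 1 (288, 51.3 to 11422) and Fezf1 176 against 1 (171, 30.4 to 6807). Rmst had 332 against 3 (108, 36.6 to 525), Pou3f2 222 against 2 (108, 29.6 to 898) and Myt1 215 against 2 (104.7, 28.6 to 870). Six3 had 96 against 1 (93.5, 16.4 to 3730) and Wnt8b 182 against 3 (59.1, 19.9 to 289). Outside the 10 largest falls, the long noncoding RNA Miat fell from 52.0 ± 2.67 to 2.27 ± 0.477 CPM (log2 fold change -4.51 ± 0.21, edgeR adjusted p = 5.1e-08). Its list of nuclear long noncoding RNAs had a median of -0.09 and was not called (camera adjusted p = 0.051). In total, 2109 genes changed at day 14, 824 higher and 1285 lower in 6A. These were 998 and 1206 with RLE, 690 and 1412 with total counts, 691 and 740 with DESeq2, and 1196 and 1244 without a filter on low counts. The count was 1016 and 982 without WT day 14 replicate 1 or 2, 1073 and 1143 without 6A day 14 replicate 1 or 2, and 1037 with an absolute log2 fold change over 1.

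**Figure D2:**
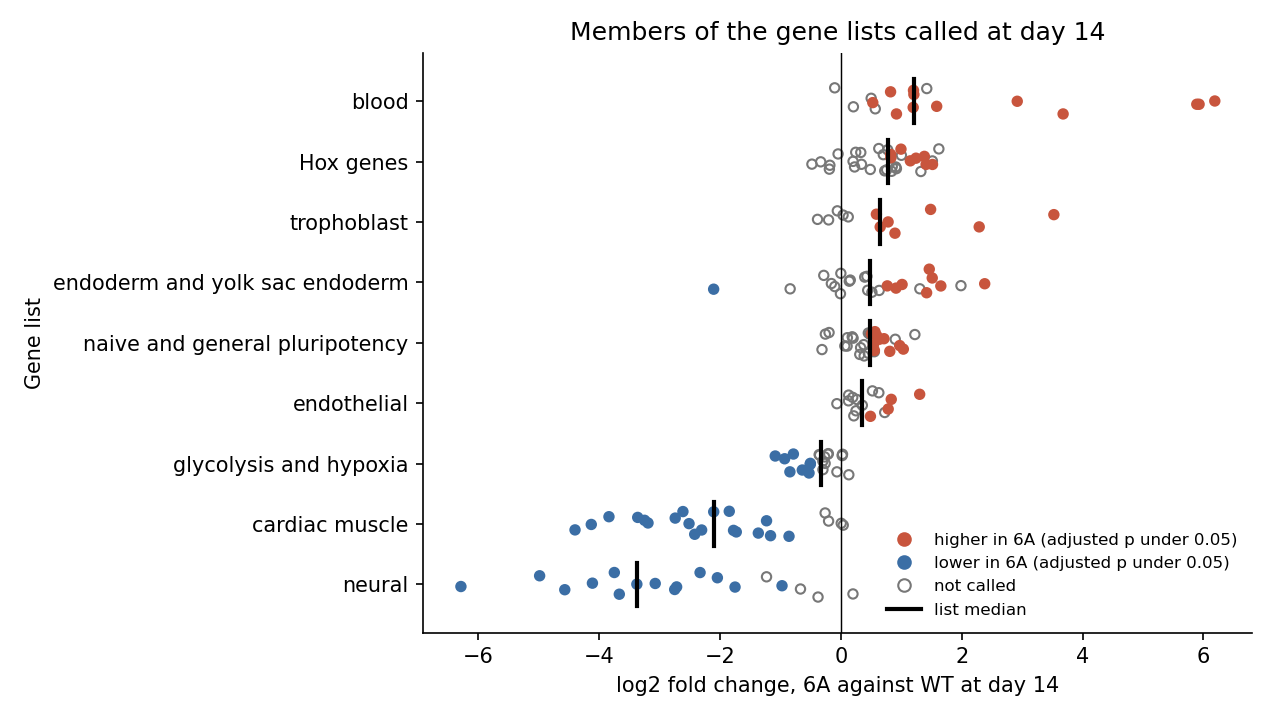
Log2 fold change of 6A against WT at day 14 for members of the 9 called gene lists, with red and blue points for members called higher and lower, open points for members not called, and black bars for list medians; members with 3 or fewer counts in a group are not drawn. Neural and cardiac muscle members lie mostly below -1, and blood members extend to 6.19.

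Progenitor and extraembryonic lists were higher in 6A at day 14, each by a smaller median. Pluripotency genes had a median log2 fold change of 0.48, with 10 of 29 members higher, or 14 higher and 1 lower adjusted over the list alone (camera adjusted p = 3.5e-06; adjusted p = 0.085 with an estimated correlation). Lin28a went from 52.5 ± 3.92 to 108 ± 2.29 CPM (edgeR adjusted p = 4.6e-05), Nr0b1 from 9.72 ± 1.00 to 19 ± 1.85, Tcl1 from 7.86 ± 0.957 to 13.9 ± 1.10 and Sall4 from 101 ± 1.42 to 147 ± 4.47. Hox genes, which pattern the body axis, had a median of 0.77 with 8 of 33 members higher, or 14 adjusted over the list alone (adjusted p = 1.6e-05; adjusted p = 0.061 with an estimated correlation). Hoxa10 rose from 9.14 ± 0.183 to 20.3 ± 0.278 CPM, Hoxc8 from 1.96 ± 0.806 to 5.84 ± 0.753 and Hoxc10 from 2.88 ± 0.627 to 6.95 ± 0.408. Endoderm and yolk sac endoderm genes had a median of 0.48 with 8 of 24 higher and 1 lower, or 12 and 2 adjusted over the list alone (adjusted p = 2.0e-05; adjusted p = 0.14 with an estimated correlation). Cubn, an endocytic receptor of yolk sac endoderm, rose from 20.1 ± 1.39 to 104.5 ± 14.7 CPM, Lama1, a basement membrane laminin, from 180 ± 5.48 to 482 ± 6.07 and Apob from 104 ± 11.2 to 210 ± 29.6. Foxa1, another member, fell from 35.4 ± 1.75 to 8.21 ± 1.64. Endothelial genes (median 0.35, 4 of 15 higher, 5 adjusted over the list alone, adjusted p = 0.00027; adjusted p = 0.27 with an estimated correlation) rose as well. Among them, the angiopoietin receptor Tek rose from 23.8 ± 3.34 to 59.1 ± 0.940 CPM, followed by Cdh5 (51.2 ± 2.04 to 91.1 ± 9.12), Tie1 (15.5 ± 0.963 to 26.7 ± 3.63) and Pecam1 (52.5 ± 1.27 to 73.7 ± 0.634). Trophoblast genes (median 0.65, 7 of 13 higher, with 7 higher and 1 lower adjusted over the list alone, adjusted p = 0.00062; adjusted p = 0.14 with an estimated correlation) were higher too. They included Cdx2 (1.04 ± 0.984 to 5.65 ± 0.0697) and Ascl2 (2.28 ± 1.21 to 6.08 ± 0.821). The bounded medians were 0.80 for Hox genes and 0.62 for trophoblast.

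Glycolysis and hypoxia genes fell at day 14, with a median log2 fold change of -0.33 and 8 of 20 members lower over all genes and over the list alone (camera adjusted p = 8.6e-05; adjusted p = 0.21 with an estimated correlation). Vegfa, the vascular growth factor, fell from 346 ± 9.79 to 163 ± 12.1 CPM (edgeR adjusted p = 5.1e-05) and Egln3 from 73.4 ± 0.588 to 38.5 ± 2.17. P4ha2, a collagen prolyl hydroxylase, fell from 121 ± 3.03 to 70.2 ± 7.53 and Pfkp, a glycolytic enzyme, from 149 ± 11.8 to 96.0 ± 0.503.

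Members of other lists changed at day 14 without a call for the list. Of the fibroblast and mesenchyme genes (median -0.10, camera adjusted p = 0.58), 2 rose and 5 fell. Dcn rose from 198 ± 6.67 to 386 ± 23.7 CPM, and Fap (3.81 ± 0.311 to 0.676 ± 0.273) and Twist1 (40.1 ± 3.66 to 23.3 ± 2.74) fell. Of the primed pluripotency genes (median 0.06, mean -0.09, adjusted p = 0.80), Zic2 (35.4 ± 3.60 to 15.8 ± 2.52 CPM), Otx2 (36.3 ± 1.94 to 18.7 ± 1.02) and Zic5 (9.79 ± 2.22 to 5.79 ± 0.275), which also mark anterior neural tissue, fell. Dnmt3b rose from 43.3 ± 3.66 to 69.2 ± 1.76. Of the Polycomb subunits (median 0.06, adjusted p = 0.15), Cbx7 (26.6 ± 1.48 to 42.4 ± 2.24 CPM), Cbx6 (113 ± 0.399 to 182 ± 27.5) and Epop, given as E130012A19Rik in the tables (25.6 ± 2.98 to 44.3 ± 3.77), rose. Of the primitive streak genes (median 0.19, adjusted p = 0.37), Fgf8 (2.38 ± 0.569 to 7.63 ± 1.5 CPM) and Mixl1 (0.764 ± 0.261 to 3.57 ± 1.5) rose and Lhx1 (4.67 ± 0.449 to 1.98 ± 0.204) fell. Of the imprinted genes (median -0.18, adjusted p = 0.81), Dlk1 (183 ± 27.1 to 314 ± 67.8 CPM) and Impact (236 ± 7.73 to 351 ± 26.1) rose and Usp29 (82.2 ± 6.48 to 46.6 ± 2.65) and Magel2 (11.5 ± 2.41 to 5.70 ± 0.957) fell. Hnrnph3 fell from 45.8 ± 1.66 to 24.9 ± 2.87 CPM in the hnRNP family (median 0.07, adjusted p = 0.77). Bgn fell from 207 ± 5.94 to 95.5 ± 13.6 among X-linked escape genes (median -0.06, adjusted p = 0.80). The X inactivation center was not called either (median 0.27, 1 of 10 members lower, or 1 higher and 2 lower adjusted over the list alone, adjusted p = 0.99).

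In the stress and growth lists at day 14, Asns (77.2 ± 1.98 to 119 ± 8.03 CPM) and Chac1 (3.84 ± 0.628 to 6.37 ± 0.138) rose and Vldlr (65.8 ± 3.28 to 44.5 ± 0.876) fell in the integrated stress and unfolded protein response (median log2 fold change 0.25, camera adjusted p = 0.063). Mdm2 rose from 169 ± 17.0 to 224 ± 6.61 CPM among p53 targets (0.19, adjusted p = 0.13). Mcm5 rose from 158 ± 5.27 to 203 ± 10 among proliferation genes (0.14, adjusted p = 0.14). The interferon response was not called (0.12, 1 of 18 members higher over all genes and over the list alone, adjusted p = 0.53). The immediate early genes Fosb (608 ± 55.5 to 891 ± 12.8 CPM), Fos (745 ± 120 to 1003 ± 87.4) and Ier3 (46.5 ± 5.71 to 63.2 ± 1.83) rose and Egr3 (53.9 ± 1.17 to 36.3 ± 6.00) fell (median 0.11, adjusted p = 0.29). Hormad1 (2.46 ± 0.126 to 4.88 ± 0.479 CPM) and the testis paralog Rpl10l (1.68 ± 0.0827 to 3.23 ± 0.888) rose in the germline list (-0.10, adjusted p = 0.81). The lists of extracellular matrix (0.13, 4 higher and 3 lower, adjusted p = 0.31), of Xist silencing and localization factors (0.10, 0.33) and ribosomal proteins (-0.03, 2 higher, 0.80) were not called. Neither were Kcnq1ot1 and Airn targets (-0.11, 1 higher, 0.87), replication-dependent histones (-0.02, 1 higher and 1 lower, 0.99) and small structural RNAs (-0.03, 0.99). Without WT day 14 replicate 1 the histone list was called higher, with a median of 0.33 (adjusted p = 0.0021). Of the 78 named genes that passed at day 14, 47 did so in every alternative. The other 31 lost the call without at least 1 library. There were 23 and 21 losses without WT day 14 replicate 1 or 2 (adjusted p up to 0.26 and 0.35), and 20 and 17 without 6A day 14 replicate 1 or 2 (up to 0.35 and 0.18). There were 4 without either 6A day 0 library (up to 0.073).

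X-linked genes at day 14 exceeded autosomal genes by a median log2 fold change of 0.079 in 6A against WT (camera adjusted p = 0.0497; adjusted p = 0.47 with an estimated correlation), with 50 genes higher and 33 lower. These counts were 20 and 14 without WT day 14 replicate 1, 26 and 14 without WT day 14 replicate 2, 30 and 10 without 6A day 14 replicate 1, and 28 and 19 without 6A day 14 replicate 2. The call was lost without WT day 14 replicate 1 (0.061) and without 6A day 14 replicate 2 (0.041). It was also lost with RLE (camera adjusted p = 0.052), without a low-count filter (0.059) and with the replicate block (0.053). The same held without escape and X inactivation center genes (0.054). Chromosome 6 was the only chromosome called in this comparison, with a median of 0.16 over 731 genes (adjusted p = 0.016). No chromosome was called in the remaining 3 contrasts, where the smallest adjusted p was 0.083, for X in the differentiation of 6A cells. Across X-linked genes, which are not independent replicates, the log2 fold change of 6A against WT was not called as related to the distance from Xist at day 0 (Spearman's rho = -0.068, permutation p = 0.033, adjusted p = 0.16 over 5 contrasts) or at day 14 (rho = 0.0042, permutation p = 0.94). The values were -0.067 for differentiation in WT (permutation p = 0.59), -0.033 in 6A (permutation p = 0.74) and 0.072 for the interaction (permutation p = 0.28), with adjusted p of at least 0.69.

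The genotype difference itself changed between the days for 733 genes, 217 with a larger value at day 14 and 516 with a smaller one (edgeR genotype by day interaction). These were 280 and 460 with RLE, 173 and 637 with total counts, 224 and 336 with DESeq2, and 416 and 568 without a filter on low counts. The neural list moved down by a median of -2.81 (12 members called lower, camera adjusted p = 2.8e-24; adjusted p = 0.015 with an estimated correlation). The cardiac list moved by -1.68 (7 called lower, adjusted p = 2.6e-11; adjusted p = 0.027 with an estimated correlation). Tubb3 had an interaction of -2.09 ± 0.19, Map2 of -2.32 ± 0.21 and Ttn of -2.44 ± 0.19 (adjusted p = 8.0e-05, 8.0e-05 and 3.1e-05). Blood genes moved up by 1.10 (4 called higher, adjusted p = 6.9e-05; adjusted p = 0.088 with an estimated correlation), with Hbb-bh1 at 6.39 ± 0.86 (adjusted p = 0.0011). Pluripotency genes moved up by 0.56 (6 called higher, adjusted p = 1.1e-08; adjusted p = 0.055 with an estimated correlation), with Lin28a at 1.26 ± 0.16 and Nr0b1 at 1.43 ± 0.18. Hnrnpk (0.17 ± 0.17, adjusted p = 0.67), Xist (-0.12 ± 0.19, adjusted p = 0.81) and Tsix (0.32 ± 0.24, adjusted p = 0.53) had none that passed. X-linked genes had a value of -0.113 against autosomal genes that did not pass (camera adjusted p = 0.077). It passed without WT day 0 replicate 1 (-0.137, adjusted p = 0.029), 6A day 0 replicate 1 (-0.141, 0.036), WT day 14 replicate 1 (-0.124, 0.049) or 6A day 14 replicate 2 (-0.137, 0.048). The count of 733 was 371 without 6A day 0 replicate 2, 350 and 280 without WT day 14 replicate 1 or 2, and 341 and 465 without 6A day 14 replicate 1 or 2. The genotype comparisons at the 2 days had 34 higher genes in common (8.74 expected from independent calls, Fisher's exact test p = 6.0e-12) and 30 lower genes (6.65 expected, p = 4.2e-13). The 2 comparisons share no library, but they come from 1 fit with a shared filter and shared dispersions. Genes are also not independent, so these p-values may overstate the overlap.

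In WT cells, differentiation lowered pluripotency genes and raised those of heart, endoderm, blood and other lineages. All 29 pluripotency genes fell, with a median log2 fold change of -3.31 (camera adjusted p = 3.6e-29; adjusted p = 0.027 with an estimated correlation). Zfp42 fell from 791 ± 5.99 to 39.0 ± 2.71 CPM (SD, n = 2; edgeR adjusted p = 1.1e-11), Esrrb from 827 ± 38.3 to 45.3 ± 0.00815 and Tfcp2l1 from 633 ± 10.9 to 45.5 ± 1.46. All 23 cardiac genes rose (median 5.99, adjusted p = 7.9e-23; adjusted p = 0.060 with an estimated correlation). Myh7 rose from 0.891 ± 0.0383 to 169 ± 1.74 CPM and Tbx20 from 0.891 ± 0.0383 to 142 ± 8.64. Endoderm genes rose (median 4.69, bounded 3.66, 21 of 24 called, adjusted p = 1.6e-10; adjusted p = 0.11 with an estimated correlation). Gata6 rose from 0.635 ± 0.20 to 257 ± 37.4 CPM and Apob from 2.24 ± 0.671 to 104 ± 11.2. Neural genes had a median of 2.90 with 17 higher and 3 lower (adjusted p = 0.0026; adjusted p = 0.12 with an estimated correlation). Tubb3 was among those that fell, from 193 ± 3.23 to 55.8 ± 8.13 CPM. Blood genes had a median of 2.32 (bounded 2.24) with 9 higher and 2 lower (adjusted p = 0.0030; adjusted p = 0.27 with an estimated correlation). The macrophage receptor Csf1r rose from 0.573 ± 0.287 to 49.6 ± 0.448 CPM. Of the 10 largest rises, Afp, the fetal liver and yolk sac protein, had 1998 counts against 1 (ratio 2091, 95% interval 375 to 82640) and Actc1 1757 against 1 (1839, 330 to 72677). The others had 0 counts at day 0. Cx3cr1 was at least 153-fold higher at day 14, Dcx at least 149-fold, Trim55 148, Alpk2 129, Pln 122, Emcn 111, Gata5 107 and Adamtsl2 96.6.

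Xist rose on differentiation in WT from 65.4 ± 10.8 to 1142 ± 22.4 CPM (log2 fold change 4.13 ± 0.15, edgeR adjusted p = 5.5e-11). In 6A it rose from 59.7 ± 7.11 to 966 ± 75.2 (4.02 ± 0.15, adjusted p = 5.7e-11). Tsix fell by 3.98 and 3.66 on the log2 scale (adjusted p = 1.8e-10 and 3.0e-10). Jpx, a noncoding activator of Xist, rose from 0.238 ± 0.162 to 5.08 ± 0.359 CPM in WT and from 0.50 ± 0.14 to 3.91 ± 1.43 in 6A. Chic1 fell from 57.9 ± 5.71 to 25.6 ± 1.41 and from 89.3 ± 3.12 to 31.5 ± 6.96. The X inactivation center as a list was not called (medians -0.42 and -0.81, camera adjusted p = 0.90 and 0.51). Hnrnpk fell by 0.71 in WT and by 0.54 in 6A on the log2 scale (adjusted p = 0.00013 and 0.0013). X-linked genes fell against autosomal genes by 0.418 in WT (adjusted p = 0.0497; adjusted p = 0.47 with an estimated correlation). In 6A they fell by 0.522 (adjusted p = 0.010; adjusted p = 0.47 with an estimated correlation). Their share of counts at day 14 was 3.5% and 3.66% in WT and 3.63% and 3.77% in 6A. The WT call was lost without WT day 14 replicate 1 (-0.389). It was also lost with RLE (camera adjusted p = 0.052), without a low-count filter (0.059), with the replicate block (0.053) and without escape and X inactivation center genes (0.058).

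The largest falls on differentiation included Y-linked genes, which mark feeder RNA. The Y-linked sum, scaled to total counts, went from a mean of 26.4 CPM in WT and 43.0 in 6A at day 0 to 0 and 0.050 at day 14. In WT, Ddx3y was at least 75.2-fold lower at day 14, Uty 51.6, Eif2s3y 47.5 and Kdm5d 25.8, all of them Y-linked. The others were Klk11 (at least 33.1-fold), Trim12a (32.2), Ube2dnl1 (20.7) and Gldn (956 counts against 2, ratio 457, 95% interval 126 to 3777). They also included the stromal protease Mmp3 (190 ± 9.27 to 0.414 ± 0.421 CPM) and Il1rl1 (272 ± 33.9 to 1.11 ± 0.231). In 6A they were Gldn (at least 397-fold), Wisp2 (161), Ddx3y (115), Eif2s3y (64.5), Prg4 (61.1), Kdm5d (46.3), Zp3 (32.6) and Klk11 (30.5). Further falls in 6A were Mmp3 (6478 counts against 3, ratio 1677, interval 574 to 8133) and Penk (425 ± 21.4 to 1.01 ± 0.205 CPM). Interferon response genes fell in both, with medians of -3.53 in WT and -3.46 in 6A and 17 of 18 members lower in each (camera adjusted p = 4.1e-13 and 5.7e-16; adjusted p = 0.11 and 0.069 with an estimated correlation). Irf7 went from 40.8 ± 4.58 to 0.527 ± 0.0743 CPM in WT and from 56.5 ± 0.280 to 0.724 ± 0.205 in 6A. Fibroblast genes rose in both, by medians of 1.95 and 1.60 with 20 higher and 3 lower in WT and 17 and 6 in 6A (adjusted p = 3.7e-07 and 5.2e-05; adjusted p = 0.14 and 0.21 with an estimated correlation). Without 156 genes marked by feeder RNA, 11494 and 10948 genes changed on differentiation in WT and 6A.

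In 6A cells, differentiation lowered all 29 pluripotency genes (median log2 fold change -3.13, camera adjusted p = 1.7e-25; adjusted p = 0.015 with an estimated correlation). Zfp42 fell from 743 ± 12.5 to 55.3 ± 1.08 CPM and Tfcp2l1 from 632 ± 10.8 to 67.0 ± 5.79. Differentiation raised blood genes by a median of 5.36 (bounded 4.96, 16 higher and 1 lower, adjusted p = 2.8e-11; adjusted p = 0.027 with an estimated correlation). Csf1r rose from 0.728 ± 0.180 to 114 ± 5.56 CPM and Hbb-bh1 from 0.228 ± 0.0398 to 29.2 ± 1.99. It also raised endoderm genes (median 4.24, bounded 4.09, all 24 called, adjusted p = 4.8e-17; adjusted p = 0.055 with an estimated correlation). Gata6 rose from 0.628 ± 0.321 to 282 ± 27.8 CPM and Apob from 2.13 ± 0.371 to 210 ± 29.6. Of the cardiac genes, 19 rose (median 3.99, bounded 3.71, adjusted p = 4.8e-11; adjusted p = 0.027 with an estimated correlation), including Tbx20 from 0.471 ± 0.183 to 143 ± 14.2. Neural genes were not called as a list (median -1.52, bounded -1.40, 5 higher and 12 lower, adjusted p = 0.18), and Tubb3 fell from 164 ± 15.2 to 11.1 ± 0.481 CPM. The 10 largest rises all had 0 counts at day 0. Afp was at least 828-fold higher, Cx3cr1 323, Tcf21 196, Cryaa 155, Emcn 145, Ifi202b 120, Adgrl4 118, Tnf 111, Pld5 107 and Klhl6 103. In total, 11630 genes changed in WT (5940 higher, 5690 lower) and 11119 in 6A (5468 higher, 5651 lower), and 7634 and 6803 did so by an absolute log2 fold change over 1. Scaling by total counts instead of TMM moved the median log2 fold change of all genes to 0.24 in WT and 0.10 in 6A, and upper-quartile scaling to 0.17 in WT. In 6A, 49.2% of the changed genes were higher at day 14 with TMM, against 52.3% with RLE and 54.6% with total counts. In WT the share was 51.1% with TMM, 52.0% with RLE, 55.9% with upper-quartile scaling and 58.4% with total counts.

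Further lists moved in the same direction in both genotypes on differentiation. Proliferation genes fell (medians -1.58 in WT and -1.49 in 6A, 19 of 20 members lower in each, camera adjusted p = 3.9e-09 and 7.2e-08; adjusted p = 0.055 and 0.061 with an estimated correlation). The S phase cyclin Ccne1 fell from 350 ± 43.9 to 43.7 ± 0.311 CPM in WT and from 306 ± 0.376 to 56.9 ± 3.63 in 6A. Ribosomal protein genes fell (-0.88 and -0.77, 75 and 69 of 81 lower, adjusted p = 3.1e-07 and 6.8e-06; adjusted p = 0.39 and 0.45 with an estimated correlation). Histones fell (-0.94 and -0.58, 39 and 24 lower, adjusted p = 0.0016 and 0.035; adjusted p = 0.68 and 0.80 with an estimated correlation), and so did X-linked escape genes (-0.81 and -0.91, adjusted p = 0.031 and 0.0056; adjusted p = 0.45 and 0.35 with an estimated correlation). Imprinted genes rose (2.03 and 1.98, 20 higher and 4 lower in each, adjusted p = 2.3e-06 and 1.6e-06; adjusted p = 0.25 and 0.22 with an estimated correlation). So did extracellular matrix (1.05 and 1.24, 14 higher in each, adjusted p = 0.00014 and 2.1e-05; adjusted p = 0.35 and 0.32 with an estimated correlation) and immediate early genes (1.79 and 1.88, 11 higher and 2 lower in each, adjusted p = 0.00053 and 2.6e-05; adjusted p = 0.28 and 0.22 with an estimated correlation). Endothelial (1.65 and 2.41, 10 and 15 of 15 higher, adjusted p = 0.0014 and 2.5e-07; adjusted p = 0.12 and 0.20 with an estimated correlation) and trophoblast genes rose (1.67 and 2.00, 7 and 9 higher, adjusted p = 0.013 and 2.6e-05; adjusted p = 0.19 and 0.11 with an estimated correlation). Germline genes fell (-1.26 and -2.52, 8 and 13 lower, adjusted p = 0.039 and 0.00049; adjusted p = 0.28 and 0.21 with an estimated correlation). The WT call was lost without WT day 0 replicate 1 (adjusted p = 0.059) and with the replicate block (0.060). The trophoblast median in WT was 0.81 to 1.07 in each fit without a library except that without 6A day 14 replicate 1. The histone median was -0.63 in WT without WT day 14 replicate 2 and -0.89 in 6A without 6A day 14 replicate 1. Histones in 6A were not called without 6A day 0 replicate 1 or 6A day 14 replicate 2 (adjusted p up to 0.081).

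Of the rest, the integrated stress response list was called in WT only (-0.69, camera adjusted p = 0.034; adjusted p = 0.21 with an estimated correlation; -0.42 and adjusted p = 0.19 in 6A). It was not called without WT day 14 replicate 2 (adjusted p = 0.056). Hox genes (1.76, adjusted p = 0.040; adjusted p = 0.21 with an estimated correlation) and primitive streak genes (2.63, adjusted p = 0.044; adjusted p = 0.23 with an estimated correlation) were called in 6A and not in WT (1.33, 0.42; 1.58, 0.24). Neither was called without 6A day 0 replicate 2 (adjusted p = 0.052 and 0.053), with RLE (0.053 and 0.054), with total counts (0.055 for both) or with the replicate block (0.063 and 0.057), nor primitive streak genes without either WT day 0 library (up to 0.059). The difference between the genotypes had an interaction adjusted p of 0.0029 for the stress response, 0.0049 for Hox and 0.042 for primitive streak genes (camera). None of the 3 passed with an estimated correlation (adjusted p = 0.14, 0.13 and 0.23). Primitive streak genes also did not pass with RLE, with the replicate block or without WT day 0 replicate 1, 6A day 0 replicate 2 or 6A day 14 replicate 1 (adjusted p up to 0.20). Not called in either genotype, with the WT value first, were the hnRNP family (-0.51, 0.061; -0.53, 0.080), Xist silencing factors (-0.47, 0.064; -0.45, 0.13) and Polycomb subunits (-0.19, 0.38; -0.06, 0.51). So were small structural RNAs (-0.63, 0.29; -0.24, 0.51), glycolysis and hypoxia (-0.09, 0.39; -0.21, 0.72), primed pluripotency (-0.51, 0.65; -0.49, 0.99), p53 targets (-0.12, 0.80; -0.10, 0.90), Kcnq1ot1 and Airn targets (-0.50, 0.90; 0.34, 0.86) and nuclear long noncoding RNAs (0.30, 0.99; -0.33, 0.51). All 36 genes named and called in WT and all 35 in 6A kept their call in every alternative.

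The allele counts, compared after seeing the data, measured the reads of each parental X chromosome, with those of feeder RNA at day 0. Both parental alleles were read on the X chromosome, on chromosomes 5, 7, 8, 9 and 13 and on parts of 2, 6 and 11, whereas the other autosomes were read almost entirely as 129. Xist came from the 129 allele in every library, with shares from 94.4% (Wilson 95% interval 90.3 to 96.9%) in WT day 0 replicate 1 to 99.0% (97.2 to 99.7%) in WT day 0 replicate 2. X-linked genes had a median 129 share of 51.4 ± 0.314% in WT and 54.2 ± 0.666% in 6A at day 0 (SD, n = 2), against 54.3 ± 0.0218% and 55.7 ± 0.151% on autosomes. At day 14 the X-linked median was 9.57 ± 0.135% in WT and 13 ± 0.0495% in 6A, against 49.5 ± 0.0304% and 49.9 ± 0.183% on autosomes. In WT the log2 ratio of 129 to CAST reads of X-linked genes fell by 2.88 against autosomal genes (333 of 432 genes called lower, camera adjusted p = 7.0e-49; adjusted p = 0.0037 with an estimated correlation). In 6A it fell by 2.44 (adjusted p = 3.3e-39; adjusted p = 0.0013 with an estimated correlation).

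**Figure D3:**
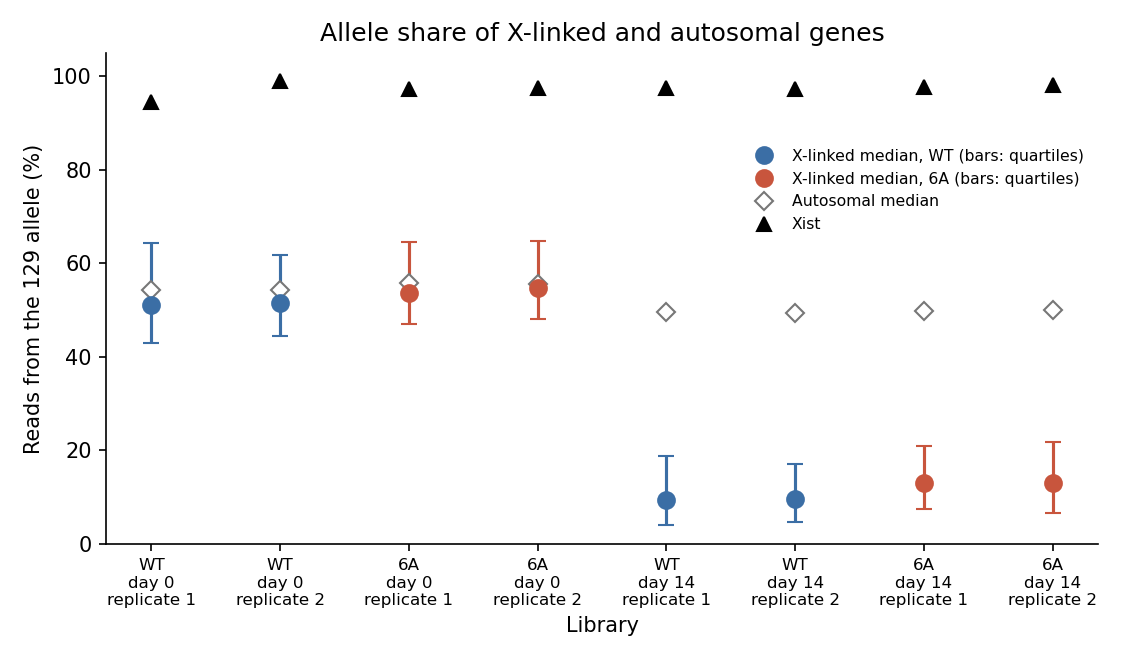
Share of reads from the 129 allele in each library, with circles for the X-linked median (bars for the quartiles, WT in blue and 6A in red), diamonds for the autosomal median and triangles for Xist. The X-linked median was 51.1 to 54.7% at day 0, 9.47 and 9.66% in WT at day 14 and 13 and 13.1% in 6A at day 14.

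At day 14 the 129 X chromosome, which expressed Xist, was read more in 6A than in WT. The log2 ratio of 129 to CAST reads of X-linked genes was higher in 6A by 0.407 against autosomal genes (331 of 432 genes higher, camera adjusted p = 5.9e-11; adjusted p = 0.0013 with an estimated correlation). Single X-linked genes called higher were Col4a6 (129 share 1.31% in WT and 4.13% in 6A), Flna (4.82 and 8.84%), Itm2a (1.21 and 3.10%), Maged1 (4.15 and 7.03%), Nrk (2.87 and 5.45%), Sh3bgrl (1.99 and 7.22%) and Wbp5 (14.0 and 27.0%). Their number, 7, was 3 without either WT day 14 library, 4 without either 6A day 14 library, 14 without either WT day 0 library, and 10 and 11 without 6A day 0 replicate 1 or 2. Among 238 X-linked genes, Xist included, with at least 100 reads in both groups, 201 had a higher share in 6A, by a median of 2.80 percent points over all 238. At day 0, 174 of them had a higher share in 6A, by a median of 2.19 percent points. In WT 121 genes and in 6A 75 had a share under 10%. The median difference was 2.82 points for genes with a WT share under 5%, 3.46 for 5 to 10%, 3.20 for 10 to 20%, 2.59 for 20 to 40% and 0.362 for the 12 genes above. Of the X-linked escape genes, 11 had enough reads (medians 17.6% in WT and 18.4% in 6A, WT shares from 2.84 to 39.1%). Over all X-linked reads the share, raised by Xist reads, was 18.1 ± 0.315% and 19.9 ± 0.123%. The share was not called as related to the distance from Xist across genes, which are not independent replicates (rho = 0.036 in WT, 0.049 in 6A and 0.089 for the difference, permutation p = 0.85, 0.82 and 0.34, adjusted p = 0.85 for each). At day 0 the ratio was higher in 6A by 0.087 (adjusted p = 0.040; adjusted p = 0.066 with an estimated correlation). The day 0 shares include feeder RNA, which was read mostly as 129 and whose Y-linked sum was 1.63 times as high in 6A. The call was lost without WT day 0 replicate 1 (adjusted p = 0.087), WT day 0 replicate 2 (0.097) or 6A day 0 replicate 2 (0.20).

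**Figure D4:**
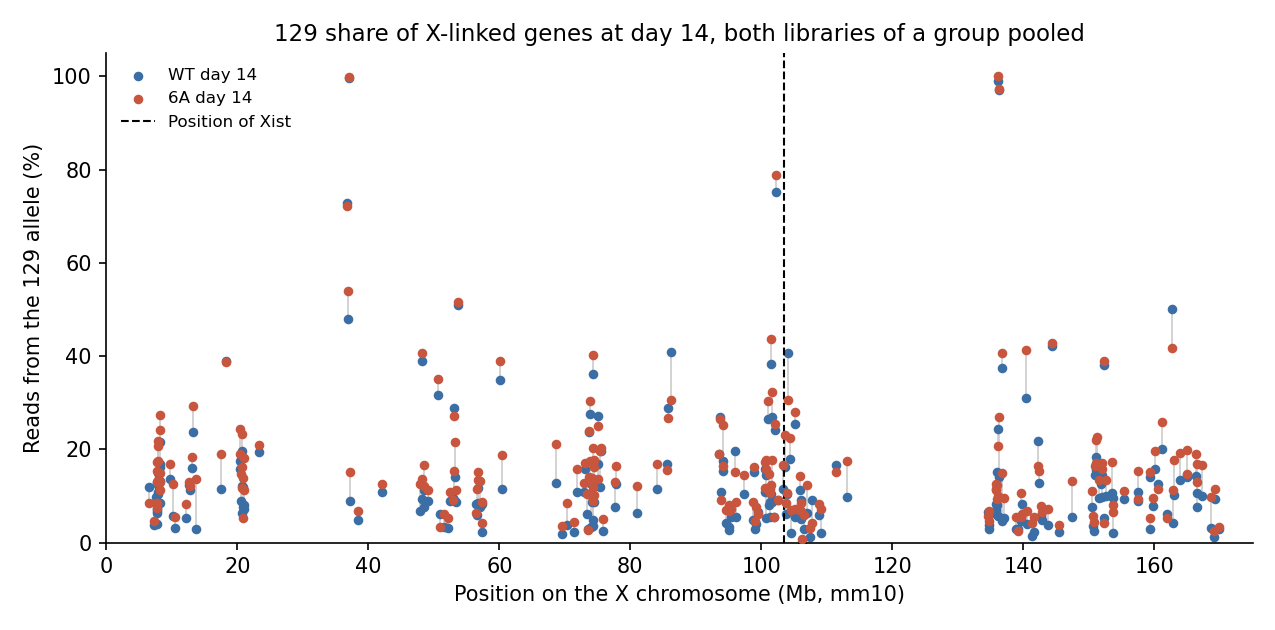
Share of reads from the 129 allele at day 14 for 237 X-linked genes other than Xist with at least 100 reads in both groups, plotted by position on the X chromosome (Mb, mm10), WT in blue and 6A in red with the 2 libraries of a group pooled, grey lines joining the values of a gene and a dashed line at Xist. Most genes lie below 20% in both groups, with the 6A point above the WT point.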

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

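Each gene and list in this part, and the allele ratio of X-linked genes, had a genotype difference at day 14 that differed from that at day 0 by the interaction test. The X-linked excess at day 0, weighed last, did not (interaction -0.113, camera adjusted p = 0.077). The comparison of allele reads was chosen after its values were seen, as were the tests of feeder RNA and of a general shift for the allele share and the tests of chromosomes and of fewer neural cells for the lineage genes. The other tests were planned before the values they measure were seen.

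Among gene lists, the interaction had a median of -2.81 for neural, -1.68 for cardiac muscle, 1.10 for blood and 0.56 for naive and general pluripotency. It was -0.48 for fibroblast and mesenchyme (camera adjusted p = 4.6e-06; 0.15 with an estimated correlation), 0.55 for endothelial (6.9e-05; 0.27) and 0.41 for replication-dependent histones (0.00047; 0.67). It was 0.90 for trophoblast (0.00049; 0.12), 0.25 for endoderm and yolk sac endoderm (0.0027; 0.22) and 0.29 for the integrated stress and unfolded protein response (0.0029; 0.14). Hox genes had 0.40 (0.0049; 0.13), ribosomal proteins 0.18 (0.0056; 0.67), proliferation 0.15 (0.0083; 0.21) and germline -0.61 (0.011; 0.27). Nuclear long noncoding RNAs had -0.16 (0.023; 0.31) and primitive streak and mesendoderm 0.53 (0.042; 0.23). The fibroblast value had the sign that more feeder RNA in 6A at day 0 gives (Y-linked sum 1.63 times that of WT). Feeder RNA is not excluded for it. The germline value had the same sign, but whether feeders supplied germline RNA was not tested. The highest adjusted p in a fit without a library was 0.20 for primitive streak, 0.099 for nuclear long noncoding RNAs, 0.36 for ribosomal proteins and 0.38 for histones. The median of some lists moved by over 1.5 times without 1 library. For endoderm it was 0.13 and 0.83 without WT day 0 replicate 1 or 2, 0.69 and 0.90 without 6A day 0 replicate 1 or 2, and 0.39 and 0.12 without WT day 14 replicate 1 or 2. For histones it was 0.77 and 0.11 without WT day 14 replicate 1 or 2, and 0.11 and 0.63 without 6A day 14 replicate 1 or 2. For ribosomal proteins it was 0.052 without WT day 0 replicate 1, 0.30 and 0.032 without WT day 14 replicate 1 or 2, and 0.064 without 6A day 14 replicate 1. Without WT day 0 replicate 2 it was 0.25 for endothelial and 0.31 for proliferation, and without 6A day 0 replicate 2 it was 0.27 for endothelial. Without WT day 14 replicate 1 it was 0.65 for Hox, -0.96 for germline and -0.25 for nuclear long noncoding RNAs. For primitive streak it was 0.86 without WT day 14 replicate 2 and 0.93 without 6A day 14 replicate 2, where germline had -1.32. Primitive streak was lost without WT day 0 replicate 1, 6A day 0 replicate 2 or 6A day 14 replicate 1. Nuclear long noncoding RNAs were lost without 6A day 0 replicate 2, WT day 14 replicate 2 or 6A day 14 replicate 1, ribosomal proteins without WT day 0 replicate 1, WT day 14 replicate 2 or 6A day 14 replicate 1, and histones without WT day 14 replicate 2 or 6A day 14 replicate 1.

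Among genes that were higher in 6A at day 0, the edgeR interaction was negative for Xlr5a -3.42 (adjusted p = 0.0059), Usp26 -2.80 (8.0e-05), Efhc2 -2.59 (0.0062), Scml2 -2.22 (8.0e-05), Dazl -1.91 (0.0017) and Postn -0.88 (0.0062). Among those that were lower at day 0 it was positive for Vrtn 3.02 (0.00050), Egr4 2.99 (0.018), Ap1m2 1.86 (0.0059), Lef1 1.76 (0.0072) and Arhgef16 1.36 (0.044). For Lgi3 and Fgf5, which had 2 counts in a group, only the adjusted p is given, 0.025 and 0.0015.

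Neural and cardiac genes had edgeR interactions of -2.32 for Map2, -3.80 for Zic1, -2.09 for Tubb3, -3.63 for Miat, -1.14 for Zic2, -0.96 for Otx2, -3.83 for Myh7, -2.44 for Ttn and -2.66 for Myh6. Low counts left only an adjusted p for Six3os1 (0.037), Hes5 (0.0036), Pou3f2 (0.0051), Myt1 (0.020), Six3 (0.0052) and Otx1 (0.049). In blood and vessel genes the values were 6.39 for Hbb-bh1, 4.31 for Slc4a1, 1.53 for Tal1, 2.58 for Gata1, 1.61 for Tek and 3.04 for Tie1, with an adjusted p alone for Hba-x (0.0012) and Pklr (0.0096).

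Among other genes, edgeR interactions were 3.10 for Ctsk, 3.0 for Xdh, 1.26 for Lin28a, 1.43 for Nr0b1, 0.62 for Sall4, 1.05 for Dnmt3b, 2.38 for Cubn, 1.09 for Lama1 and -2.92 for Foxa1. Values for matrix, hypoxia and mesenchyme genes were -1.14 for Vegfa, -0.81 for P4ha2, -2.73 for Fap, -0.99 for Twist1 and -1.60 for Bgn. The rest were 0.61 for Asns, 1.16 for Chac1, -0.98 for Usp29, 0.96 for Cbx7, 0.79 for Cbx6, 1.37 for E130012A19Rik and -1.05 for Egr3, with an adjusted p of 0.016 for Ifi202b. Of the 19 genes named and called in the interaction by size or list, 12 passed in every alternative. The calls of Ifi202b, Six3os1, Pou3f2, Otx1, Tie1, Tal1 and Gata1 were lost without at least 1 library. Leaving out 6A day 0 replicate 2 lost 6 of the 19 (adjusted p up to 1.0), WT day 14 replicate 2 lost 5 (up to 0.27), WT day 0 replicate 1 and WT day 14 replicate 1 lost 4 each (up to 0.070 and 0.13), and each of the other 4 libraries lost 3 (up to 0.18).

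The log2 ratio of 129 to CAST reads of X-linked genes had an interaction of 0.359 against autosomal genes (camera adjusted p = 2.3e-06; adjusted p = 0.0037 with an estimated correlation). The larger 129 share of X-linked reads in 6A at day 14 was not explained by feeder RNA, since the highest Y-linked sum among the 6A libraries was 0.101 CPM, or by a general shift of reads toward 129, since the autosomal median change was 0.0059. Undifferentiated cells with 2 active X chromosomes may add to it and cannot be told apart from an effect of the mutation. Pluripotency genes exceeded their WT level at day 14 by a median of 3.80% of their 6A day 0 level. The 95% interval, bootstrapped over genes, not libraries, was 2.39 to 4.86%. X-linked reads would need 6.70% of cells, too close to exclude a contribution. An effect of the mutation, a changed cell mix and differences between clones also stay open and were not tested apart.

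Neural and cardiac genes were lower and blood genes higher in 6A at day 14. A direct dosage effect of gained or lost chromosomes was argued against by the largest median of a chromosome, 0.162, which is far below the lists' medians in size. This was chromosome 6, called higher in 6A (camera adjusted p = 0.016). An indirect effect of a chromosome gain or loss in some cells was not tested. Fewer neural cells alone would raise cardiac genes (median -2.10), but their fall is part of the pattern, not an independent test. Gene length did not account for the medians, since its trend over all genes ran only from -0.028 to 0.102, and 99.5% of the neural median was kept after its removal. A changed course of differentiation in 6A is a candidate explanation, but chance differences between embryoid body cultures stay open, since the labels do not say how many cultures the 2 libraries of a group came from.

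X-linked genes were higher in 6A than in WT at day 0. Feeder RNA was argued against as the whole cause by CAST reads, which feeders hardly supply and which had an X-linked excess of 0.0997. That excess was the gap between an X-linked median of 0.0091 and an autosomal median of -0.091. Loss of the same X chromosome from some WT cells would have left the excess on 1 allele, but 129 reads had 0.218. The 129 reads include feeder RNA, which was higher in 6A at day 0. These values therefore cannot exclude such a loss together with feeder RNA. The X-linked genes that rose, testis-type ones among them, were argued against as the whole cause, since the excess was a median of 0.119 over 360 X-linked genes with at least 10 CPM, of which 19 rose. Loss of either X chromosome from some WT cells may give the same values and was not tested beyond these alternatives, and neither was an effect of the mutation.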

How the results depend on the processing

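The set without genes marked by feeder RNA and all alternatives of the allele ratio were chosen after seeing the data. The CAST read comparison at day 0 was added to the plan later, before its own values were seen. With 2 libraries per group, leaving out 1 leaves a group with a single library, so those fits also test fewer samples. Where a call or count changed and the change was not in the number of libraries or genes tested, the cause was not tested. Depth limited low-count genes, for which only bounds or ratios with intervals are given.

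Genes changed at day 0 (244) ranged from 32 to 567 without a library. They were 459 without a low-count filter, 466 with a block for the replicate number, 23 with only the 2 groups compared, which leaves fewer samples to estimate the spread, and 93 with an absolute log2 fold change over 1. By other tools they were 194 with DESeq2 and 237 with limma-voom. The count at day 14 (2109) ranged from 982 to 2759 without a library and was 1037 with an absolute log2 fold change over 1, 1431 with DESeq2 and 2160 with limma-voom. For differentiation, that limit left 7634 of 11630 genes in WT and 6803 of 11119 in 6A, and every other alternative gave between 9954 and 11985. Interaction counts (733) ranged from 280 to 835 without a library, with 560 in DESeq2 and 700 in limma-voom.

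The X-linked excess at day 0 (0.157) passed in 15 of 16 alternatives and not with an estimated correlation (0.157, adjusted p = 0.27), with a range of 0.115 to 0.20. At day 14 (0.0792) it passed in 9 of 16. It did not pass with an estimated correlation (0.0792, adjusted p = 0.47), without escape and X inactivation center genes (0.0796, 0.054), with RLE (0.0791, 0.052), without a low-count filter (0.0481, 0.059) or with the replicate block (0.0794, 0.053), and it ranged from 0.0412 to 0.109 without a library. In the differentiation of WT (-0.418) it passed in 10 of 16, but not with an estimated correlation (-0.418, 0.47), without escape and X inactivation center genes (-0.394, 0.058), with RLE (-0.419, 0.052), without a low-count filter (-0.308, 0.059) or with the block (-0.420, 0.053). Without a library it ranged from -0.465 to -0.386. In 6A (-0.522) it passed in 15 of 16, not with an estimated correlation (-0.522, 0.47). The interaction (-0.113) ranged from -0.141 to -0.0643 without a library.

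The X-linked allele ratio at day 14 (0.407) passed in 12 of 12 alternatives, from 0.387 to 0.498, and so did its changes on differentiation and its interaction (0.304 to 0.502). At day 0 (0.087) it passed in 8 of 12. It did not with an estimated correlation (0.0868, adjusted p = 0.066) and ranged from 0.0697 to 0.0912 without a library. Of 150 list tests, 71 were called, 9 with an estimated correlation, 67 with RLE and 65 to 80 without a library. Against no change, rather than other genes, fry called 80 lists. In the same test X-linked genes had medians of 0.165 at day 0 (adjusted p = 0.015), 0.0822 at day 14 (0.18), -0.37 in WT (0.014) and -0.539 in 6A (0.0038), and their allele ratio had 0.413 at day 14 (0.00028). Abundant small structural RNAs at day 0 ranged from -0.791 to -0.0329 without a library, and replication-dependent histones at day 14 (-0.018) from -0.348 to 0.332. The direction of the test reversed for the former without WT day 0 replicate 1 (-0.0329, adjusted p = 0.81) and for the latter without WT day 14 replicate 1 (0.332, adjusted p = 0.0021), and the cause was not tested. Of the 207 named pairs of gene and comparison, 200 were called, 176 with DESeq2, 189 with limma-voom, 196 with RLE and 158 to 194 without a library. No called pair changed sign in these fits. Of those not called, Xist at day 0 and in the interaction and Tsix at day 0 did in at least 1 fit.

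The replicate numbers share only a number, and whether they pair libraries across groups is not given in the sources used here. Deviations of replicates from their group means were weakly correlated between groups (r from 0.0081 to 0.32). With the number as a block, 466 genes changed at day 0 against 244, while the counts at day 14 (2534), for differentiation (11947 and 11484) and for the interaction (1018) stayed within 1.5 times their values.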

Other observations

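Hnrnpk reads came mostly from the 129 allele, with 92.7% of 7998 reads, although 20 heterozygous neighbouring genes on chromosome 13 had a median of 52.2% (31.4 to 76.1%). The share was 91.8 ± 2.30% in WT and 93.8 ± 1.61% in 6A at day 0 and 91.2 ± 2.53% and 93.4 ± 2.40% at day 14 (SD, n = 2). It was looked at after the allele counts were seen, and the way reads were given to an allele is not given in the sources used here.

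Among single X-linked genes at day 14, pooled over the libraries of a group, Kdm5c had a 129 share of 38.2% in WT and 39.0% in 6A, Kdm6a 39.1 and 38.7%, and Utp14a 39.0 and 40.7%. Ddx3x had 23.8 and 29.4%, Usp9x 16 and 18.4%, Rlim 10.3 and 10.7%, and Atrx 11.3 and 14.2%.

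The remaining lists in the interaction were not called. Their medians were -0.22 for the X inactivation center (camera adjusted p = 0.23), 0.10 for Xist silencing factors (0.26), -0.12 for X-linked escape genes (0.26) and 0.05 for the hnRNP family (0.52). For Polycomb subunits the adjusted p was 0.39, with 3 members higher. Primed pluripotency had 0.21 (0.073), imprinted genes -0.16 (0.46), Kcnq1ot1 and Airn targets -0.24 (0.90), p53 targets -0.02 (0.65) and glycolysis and hypoxia -0.09 (0.090). Interferon response had -0.17 (0.56), immediate early genes 0.19 (0.11), extracellular matrix 0.02 (0.38) and small structural RNAs 0.56 (0.21).

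Lists with fewer than 5 tested genes were not tested as lists. Of the 2-cell-like list, Eif1a rose by 0.46 in 6A at day 14 (edgeR adjusted p = 0.025), while Zscan4a (1.44, adjusted p = 0.54, at day 0 and -1.35, 0.18, at day 14) and Sp110 (-0.24, 0.94, and 0.20, 0.85) did not pass. Of the Y-linked list, Uty (0.77, 0.10), Kdm5d (0.88, 0.12), Eif2s3y (0.45, 0.39) and Ddx3y (0.68, 0.11) did not pass in 6A against WT at day 0. The ribosomal precursor Rn45s took 0.725% to 2.79% of the counts of a library.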
